A study of Homo sapiens with 2 samples.

How the data were processed

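The data are 2 single-colour Agilent arrays (Cy3) of 1 design, from total RNA of PANC-1 cells with 100 µM chloroquine diphosphate for 12 h and of control cells. Groups were taken from the labels' treatment field. The scanner files hold the intensity of each spot, extracted with Agilent Feature Extraction 12.0.3.1 per the file headers, with background subtraction and detrending and no normalization between arrays. Spots of the chloroquine array were located with a grid file and those of the control array with the grid of the array design, per the file headers. The deposited intensity values of the chloroquine array carry at most 3 significant digits in 100% of probes, and those of the control array in 0.0097%. The authors' value table, for 176082 probes, is on a log2 scale, which was found by setting it against the scanner values: slopes were 0.969 for chloroquine and 1.02 for control, with correlations of 1.00 across probes. Its columns have medians of 5.90 and 5.90 and nearly equal quantiles. The direction is that of the scanner values, and the normalization behind it is not given in the sources used here.

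Each array has 180880 spots, of which 176026 are non-control probes of 60 bases. The median processed signal was 56.4 on the chloroquine array and 62.6 on the control array, against medians of 1.86 and 2.08 over 600 negative control spots. The number of arrays limits the precision. The processed signal was taken to log2 and each array's 75th percentile over non-control probes was subtracted (log2 values of 8.11 and 8.05). A probe was measured if it was well above background on both arrays, unsaturated, and free of outlier flags on either. The difference is chloroquine minus control, and the threshold was a log2 difference of 1, which is 2-fold. Brightness is the mean normalized log2 signal of both arrays, and groups by brightness were cut at quantiles of measured probes. For a probe well above background on 1 array only, the fold is a lower bound: its normalized signal against the higher of the lowest well-above-background signal on the other array and its own signal there.

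All gene name cells of non-control probes repeat the probe name, and 0 probe names were found in the gene tables given, so no probe could be named by gene and no coordinates are given. The 36 gene lists and the named mRNAs that were fixed before the data were examined were therefore not used, and neither were the mRNA and lncRNA split or the host genes. The rule for named RNAs kept 1 part: the 5 circRNAs with the largest difference each way among measured probes brighter than their median. The same part asks for 5 long non-coding RNAs each way; only 2 LNCV6 probes each way are named, since the files do not pair their numbers with genes. The linear probes of the array design replaced the host genes. Of the 4 kinds of linear probe, 1 shares a median of 50 bases in a row with the circRNA probe, and the others share medians of 6, 10 and 11.

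A pixel CV was set against measured probes within 0.5 of the normalized log2 signal on the same array. Probes overlap where they share 14 or more bases in a row, which does not show that they report the same RNA. Families joined circRNA probes with a shared 25-base stretch held by at most 40 probes. Pairs on opposite strands share 25 bases with the reverse complement. Groups of LNCV6 or circRNA probes holding a short sequence element were set up after the files were opened and before any of their values were seen. The median of each was placed among 10000 random lists of equal size matched on 20 bins of brightness, as a description of these libraries.

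Alternatives fixed before the data were examined were normexp background correction with an offset of 50 followed by quantile normalization, median scaling, quantile normalization, a loess fit on brightness with a span of 0.3, the authors' table, no filter on dim probes, a filter to probes brighter than the median measured probe, and a looser definition of above background. Scaling to the spike-in probes was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Intervals of a slope are 95% intervals of a linear fit. The threshold step was tested on simulated data of 129348 probes for chloroquine against control. These were the control array's values set against a copy with random spread as among probes of identical sequence. Of 200 planted 4-fold differences 100% passed the threshold, of 200 planted 2-fold differences, which lie on it, 48.0% did, and 0 other probes passed. That spread leaves out culture, labelling, hybridisation and the trend with brightness, so the 0 does not speak to false calls between the 2 arrays. With simulated random lists of probes independent of each other, 9 of 200 fell outside the central 95%.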

Results

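The study asked how the RNA content of PANC-1 cells differs when autophagy, the degradation of cell material in lysosomes, is blocked. PANC-1 is an established human pancreatic cancer cell line. Chloroquine is a weak base that accumulates in lysosomes and hinders the degradation of autophagosomes. One sample had received 100 µM chloroquine diphosphate for 12 h, and the control had grown in medium alone. Total RNA of each sample was hybridised to 1 single-colour array with probes of 60 bases, so that there was 1 array per group, 2 in all. There are no replicates, no test could be run, and every difference below describes these 2 libraries. Each array lay on its own slide and was scanned and extracted on its own, with spots located in different ways, so slide, scan, extraction and treatment cannot be told apart. The array held 88371 probes for circular RNAs (circRNAs), which are joined end to end by back-splicing and are listed by their circBase numbers. A further 87276 probes carry LNCV6 numbers. The series covers mRNAs and long non-coding RNAs, and the files separate neither these kinds nor pair the LNCV6 numbers with genes, so these probes were treated as 1 class. On the chloroquine array 79297 circRNA and 48400 LNCV6 probes were well above background, against 79343 and 49641 on the control array.

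Of 77741 circRNA probes measured on both arrays, 3826 were 2-fold or more higher in the chloroquine library (4.92%) and 5008 were 2-fold or more lower (6.44%). Of 45177 measured LNCV6 probes, 3480 were 2-fold or more higher (7.70%) and 5690 lower (12.6%). At 4-fold the counts were 339 higher and 327 lower for circRNAs, and 729 higher and 873 lower for LNCV6 probes. The split between higher and lower depended on the scaling. Among circRNAs 2-fold or more apart, 43.3% were higher in the chloroquine library; this share was 70.2% with scaling to the median, 54.2% with quantile normalization, 55.8% with normexp and quantile normalization, 56.3% after a loess fit on brightness, 54.7% in the authors' table, and 68.7% with scaling to the E1A spike-in probes. For LNCV6 probes the share was 37.9%, and 56.7% and 55.7% with scaling to the median and to the spike-ins. It was 43.9% with quantile normalization, 42.6% with normexp and quantile normalization, 45.2% after loess and 44.0% in the authors' table. Median scaling moved every difference upward by 0.21 on the log2 scale and spike-in scaling by 0.20. Probes of identical sequence at different places differed from each other with an SD of 0.12 in their log2 difference (150 probes of 72 sequences), while the SD over all measured probes was 0.74. That SD covers the array surface only, and leaves out culture, labelling and hybridisation.

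Differences went with brightness. The median log2 difference was -0.35 in the dimmest of 10 equal groups of measured probes and 0.37 in the brightest. The 9 E1A spike-in probes that were above background on every spot had differences from -0.50 to -0.02. Their slope on brightness was 0.020 (95% interval 0.0011 to 0.0386), and the slope of measured probes over the same range was 0.0784.

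**Figure D1:**
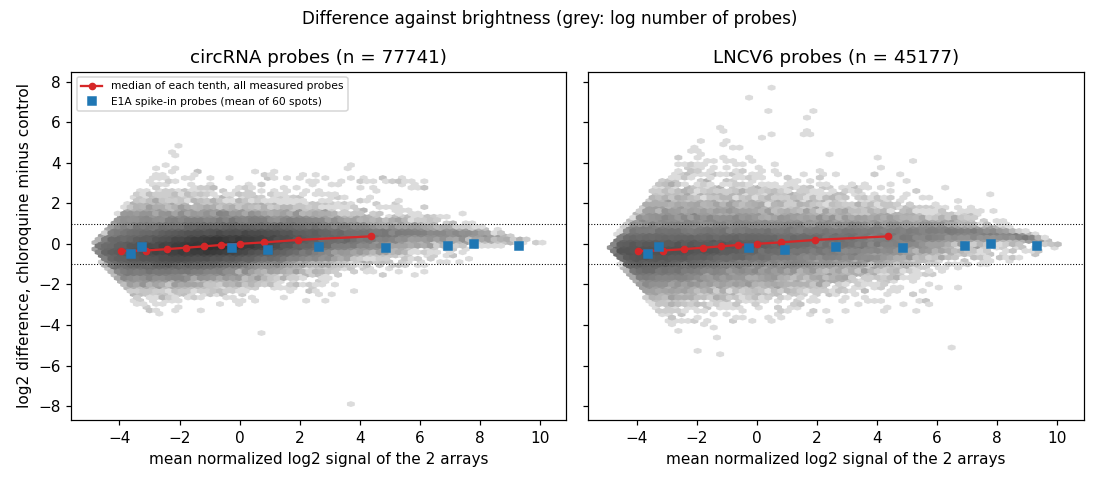
Log2 difference (chloroquine minus control) against the mean normalized log2 signal for 77741 circRNA and 45177 LNCV6 probes; darker grey stands for more probes, red points are medians of 10 equal groups by brightness, blue squares are spike-in probes and dotted lines mark 2-fold. The red medians run from -0.35 to 0.37, and the blue squares lie between -0.50 and -0.02.

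LNCV6 probes were 2-fold or more apart more often than circRNA probes at each level of brightness. With measured probes parted by brightness into 3 groups of equal size, the shares in the dim group were 21.6% of 18839 LNCV6 probes and 16.6% of 22213 circRNA probes. In the middle group they were 20.9% of 11018 and 9.68% of 29945, and in the bright group 18.3% of 15320 and 8.78% of 25583. The ratio of these shares was 1.30, 2.15 and 2.08. Without a filter on dim probes the ratio in the dim group was 0.895, the opposite order.

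The circRNAs highest in the chloroquine library, among those brighter than the median measured probe, included 2 that share most of their probe. They were hsa_circ_0048419, with probe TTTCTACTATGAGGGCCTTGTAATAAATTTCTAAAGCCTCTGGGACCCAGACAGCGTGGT, and hsa_circ_0048417. Their log2 differences were 3.89 and 3.78, folds of 14.8 and 13.7. Of the probes that share 14 or more bases with them, 3 of 5 and 1 of 4 were 2-fold or more higher, and 1 probe that overlaps both was at -1.65. Next came hsa_circ_0022567 (3.55), with 3 of 4 overlapping probes 2-fold or more higher and the other at -1.81, and hsa_circ_0022568 (3.46), whose 4 overlapping probes were higher by 2.89 to 3.35. The fifth, hsa_circ_0026373, was higher by 3.41; of 19 probes that share 14 or more bases with it, 4 were 2-fold or more higher, and their median was 0.25.

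The lowest circRNA was hsa_circ_0090398, with probe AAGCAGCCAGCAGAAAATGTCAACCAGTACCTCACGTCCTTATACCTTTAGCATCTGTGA and a log2 difference of -7.90. Its 4 overlapping probes had differences of -0.05 to 0.20. The variation among the pixels of its bright spot (CV 0.203) was above the central 95% of 676 measured probes of similar signal (0.0231 to 0.125), and 1 spot gave the value. Then followed hsa_circ_0001596 at -4.39, hsa_circ_0083244 at -2.96, hsa_circ_0011586 at -2.90 and hsa_circ_0011582 at -2.88. The bright spots of the other 9 named circRNAs lay within that range for their own signal. Of the 4 probes that overlap hsa_circ_0001596, 1 was 2-fold or more lower; the 2 that overlap hsa_circ_0083244 were at -0.24 and -0.12, and the 1 that overlaps hsa_circ_0011586 was at 0.28. Of the 2 probes that overlap hsa_circ_0011582, the LNCV6 one was lower by a similar amount (-2.81) and the circRNA one was not (0.07).

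Many circRNAs share exons, and their probes share sequence. Grouping circRNA probes by shared stretches of 25 bases gave 3583 families with 4 or more measured members, a grouping chosen after the data were seen. The median of 131 families was 2-fold or more higher and that of 150 was 2-fold or more lower. Members partly measure the same bases and are not independent. The highest were 4 circRNAs of the family of hsa_circ_0022553 (median 3.55), 7 of the family of hsa_circ_0022550 (3.26) and 4 of the family of hsa_circ_0015289 (3.18). All members of these were 2-fold or more higher. The first 2 families interleave in number and may not be independent of each other. The circRNA hsa_circ_0022567, named above, belongs to the first, and hsa_circ_0022568 lies in the same run of numbers. The lowest were the 6 of the family of hsa_circ_0020663 (-2.26), 11 of the family of hsa_circ_0044502 (-2.12, of which 9 were 2-fold or more lower) and 7 of the family of hsa_circ_0040884 (-1.98). These 6 medians kept their sign under every setting tried, and the smallest in size was 1.71. Scaling to the median or the spike-ins shifts all differences by 0.21 or 0.20, which could not turn signs of this size. The counts of families did move: median scaling gave 244 higher and 89 lower, and normexp with quantile normalization gave 53 and 38.

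**Figure D2:**
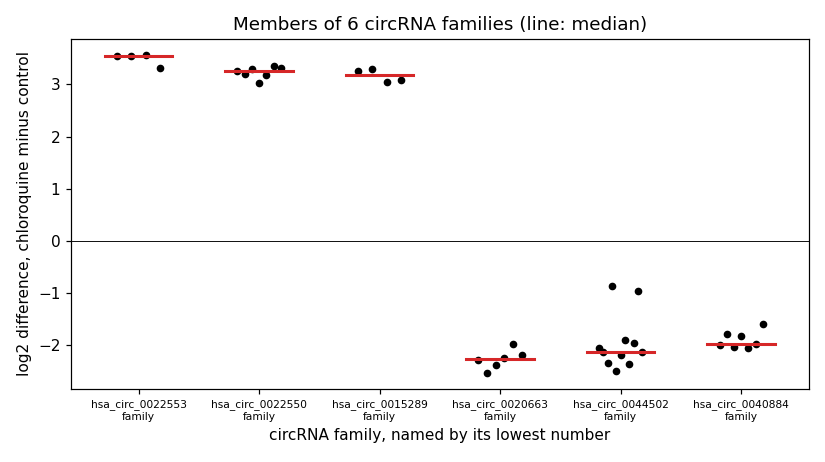
Log2 difference (chloroquine minus control) of each measured member of 6 circRNA families, with the median as a red line. Members of the 3 higher families lie between 3.03 and 3.57, and 2 members of the hsa_circ_0044502 family, at -0.86 and -0.95, stand above the other 9.

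A circRNA can move with the linear RNA of its gene. The array carries up to 4 further probes for each of 100 circRNAs, named by the circRNA with a suffix. That these report linear RNA of the same gene was inferred from the names and from the bases shared with the circRNA probe, and is not stated in the files. As linear probes they stood in for the host genes, which the files do not name. In 92 sets with a measured circRNA and linear probe, the circRNA's difference and the mean linear difference had Pearson r = 0.88 and Spearman rho = 0.86 across sets, which are not independent replicates. Without the 2 sets farthest from the median linear difference r was 0.86. By kind of linear probe r was 0.86 for the kind that shares a median of 50 bases with the circRNA probe, and 0.84, 0.82 and 0.76 for those that share medians of 11, 6 and 10. The circRNA minus linear difference had a median of 0.08 and an SD of 0.30. In 2 sets the circRNA was 2-fold or more above its linear probes, and in 0 it was as far below. These were chosen after their values were seen: hsa_circ_0008934 was higher by 0.89 with a linear mean of -0.51, and hsa_circ_0008285 was higher by 1.41 with a linear mean of 0.33.

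**Figure D3:**
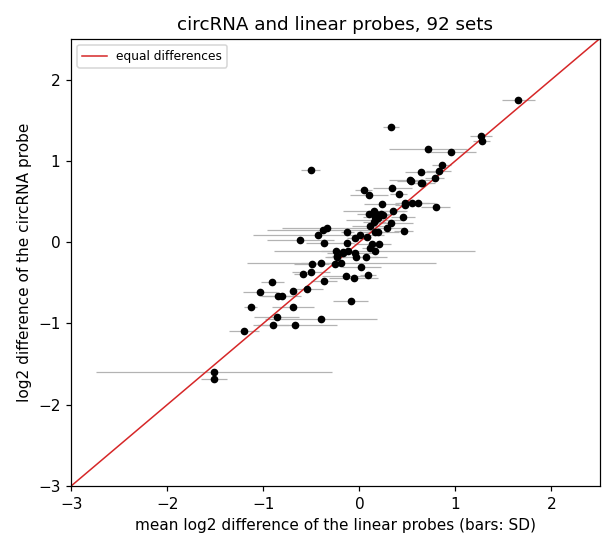
Log2 difference of the circRNA probe against the mean of its linear probes in 92 sets, with the SD of the linear probes as horizontal bars and the line of equal differences in red. Points follow the line (r = 0.88), and the 2 circRNAs farthest above it are those that differ by 1.08 and 1.40 from their linear probes.

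Among LNCV6 probes measured on both arrays and brighter than the median measured probe, the highest were LNCV6_140461_PI430048170 (7.70) and LNCV6_120229_PI430048170 (7.15). The first has the sequence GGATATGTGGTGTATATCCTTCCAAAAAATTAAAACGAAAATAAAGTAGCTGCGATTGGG, and the signal was 5220 on the chloroquine array and 24.1 on the control array. The 4 measured probes that overlap it were lower, from -0.90 to -0.44, and the 2 that overlap the second were at 1.60 and 0.29. The lowest were LNCV6_121012_PI430048170 (-5.13) and LNCV6_128690_PI430048170 (-3.82), with 1 overlapping probe each, at -0.21 and -0.68. The bright spots of these probes had pixel CVs of 0.0463, 0.0759, 0.0322 and 0.106, within the central 95% of measured probes of similar signal. Under normexp with quantile normalization the 2 higher ones were at 5.90 and 5.17; their signals on the control array, 24.1 and 19.1, were low.

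Some RNAs were well above background on 1 array only. On the chloroquine array alone this held for 1516 circRNA and 3179 LNCV6 probes, and on the control array alone for 1563 and 4426. The difference was at least 2-fold for 346 and 1048 of the former, and for 579 and 1689 of the latter. The largest bound among circRNAs was that of hsa_circ_0007091, at least 37.7-fold higher in the chloroquine library, named after its value was seen. With the looser definition of a signal above background, circRNA probes numbered 1183 on the chloroquine array alone and 1004 on the control array alone, the opposite order. The circRNA probes with a bound of at least 2-fold then numbered 507 and 605, which kept their order, and the LNCV6 probes 1849 and 3108.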

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

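Apart from the E1A spike-ins used above, the array's control probes entered no comparison. Of those above background on most spots of both arrays, 2 were higher on the chloroquine array than on the control array by more than 2 SDs of their 4 spots: DCP_22_6 by 0.28 (SD 0.05) and DCP_22_7 by 0.45 (SD 0.14), both on the log2 scale. Of the 16 DCP probes above background, 10 were lower by more than 2 SDs, from -0.40 to -0.08. DCP_22_0 was at -0.24 (SD 0.03) and DCP_20_1 at -0.40 (SD 0.02). From DCP_22_0 through DCP_22_2, DCP_22_4, DCP_22_6 and DCP_22_7 the signal fell while the difference rose: -0.24, -0.14, -0.07, 0.28 and 0.45. This order is opposite to the trend of measured probes with brightness. In the DCP_20 series the difference reached 0.14 (SD 0.13) at DCP_20_7, but the dimmer DCP_20_9 was at -0.32 (SD 0.62). Over all 31 control probes above background, E1A spike-ins included, 17 were lower by more than 2 SDs. The counts depend on the scaling: with scaling to the median, 10 of the 31 were higher and 3 lower by that measure. With scaling to the E1A spike-ins, chosen after the data were seen, 8 were higher and 3 lower. The 31 include the 9 E1A probes that set this scaling, and of the 16 DCP probes alone 7 were higher and 3 lower. DCP_22_6 and DCP_22_7 stayed higher: by 0.49 and 0.66 with median scaling, and by 0.48 and 0.65 with spike-in scaling. What these controls contain is not given in the sources used here, and no explanation was tested.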

How the results depend on the processing

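Spike-in scaling, and sequence elements without a filter on dim probes, were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group has 1 array. Not run were the slide as a block, since each slide holds 1 group, the mean over a gene's probes, and everything on gene lists, since no probe has a gene name. The 160 alternative values of named probes and families kept their sign. The smallest in size were 2.09 for a probe and 1.71 for a family. Filters leave a probe's own value as it is by construction. Median and spike-in scaling shift all differences by 0.21 and 0.20, too little to turn these signs. Normexp with quantile normalization gave 1473 circRNAs higher and 1167 lower, 1706 LNCV6 probes higher and 2295 lower, ratios of LNCV6 to circRNA shares of 2.96, 3.38 and 2.72 in the dim, middle and bright groups, 53 families higher and 38 lower, and an SD among identical probes of 0.0897. Median scaling gave 6781 circRNAs higher and 2879 lower, ratios of 1.95 and 1.58 in the middle and bright groups, and 244 families higher and 89 lower. Spike-in scaling gave 6543 circRNAs higher and 2980 lower, ratios of 1.98 and 1.61 in those groups, and 234 families higher and 89 lower. The ratio in the bright group was 2.42 with quantile normalization, 2.45 after loess and 2.44 in the authors' table. Without a filter on dim probes 7123 LNCV6 probes were higher and 13378 lower, and the ratio was 0.895 in the dim group, in the opposite order, and 1.70 in the middle group. Among probes brighter than the median measured probe, a smaller set, 2282 circRNAs were higher and 1289 lower, 2009 LNCV6 probes were higher and 1859 lower, the ratios were 2.42, 2.62 and 1.70, families numbered 82 higher and 36 lower, r between circRNA and linear probes was 0.93, and the SD among identical probes was 0.0654. The looser definition of above background gave 1004 circRNA probes on the control array alone, and 1849 and 3108 LNCV6 probes with a bound of at least 2-fold on the chloroquine and control arrays. Apart from the smaller number of probes under a stricter filter, the cause was not tested. The correlation of circRNA and linear differences was between 0.85 and 0.88 under the other settings, and the median circRNA minus linear difference was positive under all of them. In the dim group, nearest to background, 18.9% of all measured probes were 2-fold or more apart, against 12.3% in the bright group; why they differ was not tested.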

Other observations

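The tests of base composition were set before their result was seen, and the other tests here after. Probes were grouped by short sequence elements with known roles in mRNAs. A Pumilio site, bound by proteins that repress mRNAs, lay in 378 measured LNCV6 probes; 27 were 2-fold or more higher and 61 lower, and their median difference of -0.23 was below all 10000 random lists matched on brightness. The AU-rich nonamer of many short-lived mRNAs lay in 192 probes, with 19 higher, 33 lower and a median of -0.29, at percentile 0.090. The median of all measured LNCV6 probes was -0.14, with 7.70% 2-fold or more higher and 12.6% lower. Probes with the AU-rich nonamer exceeded both of these shares. Those with a Pumilio site exceeded only the share of lower probes. Random lists were drawn probe by probe, while probes of one RNA or of shared sequence can move together. The percentiles given here may therefore be too extreme. A polyadenylation signal lay in 5425 probes, whose median of -0.02 was at percentile 67.4. The 24 probes with the histone 3′ stem-loop had a median of -0.38 at percentile 8.50. The C2H2 zinc finger linker peptide, in 18 LNCV6 and 9 circRNA probes, gave percentiles of 79.3 and 91.8. The protein kinase catalytic loop, in 25 circRNA probes, was at 67.6, and the DEAD box of RNA helicases, in 5 circRNA probes, at 96.1. Both Alu elements, and the latter 2 motifs in LNCV6 probes, had under 5 measured probes each.

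The lower medians of probes with a Pumilio or AU-rich site are a hypothesis about shared regulation. Matching on brightness and GC content left them at percentiles 0.010 and 0.28. Within the limit of lists drawn probe by probe, this argues against brightness and GC content as the cause. Base composition was tested by shuffling the sites: 1.52% of 264 shuffled Pumilio sites and 0.397% of 252 shuffled AU-rich sites had a median as low after loess. Some shuffled sites can still match the real one. The shuffled site TGTAAAT with any base after it, at -0.25, can hold a Pumilio site. Shuffled sites also overlap one another, so these percentages are approximate. The sites were at -0.22 and -0.27 after loess, and the shuffled sites had medians of -0.07 and -0.09, against -0.05 for all LNCV6 probes. The lowest shuffled sites were at -0.31 and -0.31, below the sites themselves. A loss confined to 3′ ends would lower probes with a polyadenylation signal relative to probes elsewhere. They stood at percentile 67.4, and at 17.7 after loess. Where the other probes lie on their RNAs is not known here. If most lie near 3′ ends, a general loss would lower the random lists too, so these percentiles cannot decide it. With median scaling the medians were -0.01 and -0.08 against 0.07 for all LNCV6 probes. Without a filter on dim probes the medians were -0.23 and -0.24 against -0.21 for all LNCV6 probes, a gap of only 0.01 and 0.02 in size, although still below all 10000 lists matched on brightness and at percentile 0.57. Treatment, slide, scan and extraction stay open, since each group is 1 array.

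The agreement of circRNA and linear probes may come from linear RNA bound by circRNA probes, or from RNAs of one gene that move together. The SD of circRNA minus linear differences was 1.03 times that of linear minus linear differences (95% bootstrap interval 0.806 to 1.44, 72 sets with all 5 probes), a value that either would give, so they cannot be told apart. By kind of linear probe, r was 0.86 where a median of 50 bases is shared and 0.84, 0.82 and 0.76 where medians of 11, 6 and 10 are. Shared bases alone are argued against for the agreement among neighbouring circRNAs. Those of consecutive numbers whose probes share no 14-base stretch had r = 0.49 across 49145 pairs, while the highest of 100 random pairings was 0.015. The 19644 pairs that do share such a stretch had a higher r of 0.77, so shared bases may still add to it. These pairs hold circRNA probes only and do not test the agreement with linear probes.

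Probes for opposite strands of a nearly identical stretch had large and opposite differences. LNCV6_121012_PI430048170, with the sequence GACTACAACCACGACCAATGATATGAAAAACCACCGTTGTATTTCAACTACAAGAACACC, was lower in the chloroquine library, at -5.13, and 2 probes for the opposite strand were higher by 5.59 and 5.37. The longest stretch that it shares with the reverse complement of either is 33 bases, and the probes are not exact complements of each other. The 2 higher probes lie at separate places, and the smaller value of 5.37 argues against a fault of one spot for that strand. For the lower strand, where 1 probe was measured, the pixel CV of the bright spot on the control array was 0.0322. That of its spot on the chloroquine array was 0.149. A range from probes of similar signal was computed for the bright spot only, so a fault on the chloroquine array cannot be told apart. An exchange of strands throughout one array's labelling would give a negative r. Across the other reverse-complementary pairs, 2 fewer than the 531 in all, r was 0.20 (95% bootstrap interval 0.0743 to 0.330). Over all 531 pairs r was 0.000219. Some probes are in several pairs, so the interval may be too narrow. Of 27 pairs with both differences at 2-fold or more, 9 had opposite signs. Slide, scan, extraction and treatment stay open.

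Of the 6 LNCV6 probes numbered within 3 of LNCV6_140461_PI430048170 in the design, the 3 with higher numbers were well above background on the chloroquine array only, and the 3 with lower numbers were measured on both arrays, with differences of 0.92, 0.15 and 0.55. Of the 3 with higher numbers, LNCV6_140463_PI430048170 was dim, at a normalized log2 signal of -2.93 on the chloroquine array. The lowest signal well above background on the control array was -4.80, so its bound is far smaller than those that follow. Of those on the chloroquine array only, the probe with sequence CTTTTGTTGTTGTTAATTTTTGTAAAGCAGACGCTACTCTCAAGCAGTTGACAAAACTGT was at least 401-fold higher there, and the probe with sequence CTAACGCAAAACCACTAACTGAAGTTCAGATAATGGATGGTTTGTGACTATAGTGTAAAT at least 98.2-fold.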
